A study of Homo sapiens with 6 samples.

How the data were processed

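Total RNA from BCPAP papillary thyroid carcinoma cells was hybridised to Affymetrix PrimeView arrays, which read transcripts near their 3' end. Per the labels' protocols, cells were transduced with lentivirus carrying a hairpin against CSF2 or a non-targeting hairpin, and puromycin selection began after 48 hours and lasted 7 days. Labelled cRNA was made from 200 ng of total RNA. Samples were grouped by their titles into shCSF2 (n = 3) and shCtrl (n = 3), which the labels describe as biological replicates. The hairpin sequences and the number of hairpins per gene are not given in the sources used here.

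The values deposited by the authors are log2 expression summaries, 1 per probe set and array. The submitters' processing notes name RMA, oligo and limma, without versions or the role of each, and the range and near-equal quartiles of the arrays fit RMA output. RMA corrects background, normalises between arrays and summarises probes by median polish, which compresses differences at low signal. Probe-level files were not used here, so the background correction and normalisation could not be varied at that level. All 6 columns of the table were mapped to samples.

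Probe sets were named through the platform annotation. Of 49395 probe sets, 102 were controls. Of the other 49293, 44988 were paired with 1 gene symbol, 1832 with several and 2473 were not listed. Symbols were updated through gene identifiers against a RefSeq gene table of GRCh38.p14, where 27 probe sets did not match and 0 symbols changed. Probe sets paired with several genes or with none named no gene. The probe set with the highest mean over the 6 arrays represented each gene, which gave 18132 genes, of which 11734 had more than 1 probe set. The design called for the CSF2 probe sets to be reported first, but 0 probe sets were paired with CSF2, alone or with other genes, so its level is not analysed here. Genome coordinates are not given, since no build belongs to the array values.

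Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, filter or trend, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Log2 fold changes are shCSF2 minus shCtrl and are given with their moderated standard errors. Figures were drawn with matplotlib 3.10.9. Before the data were examined, the design, the alternatives, 25 gene lists and the rule for named genes were fixed. The rule took, in each direction, the 14 genes with the largest absolute log2 fold change that passed, had no overlap between groups and had a mean log2 value of at least 6 in the higher group. From each list it took the 4 passing members with the largest change, or 2 members where none passed, and the text gives examples from these. Genes outside the rule are described as chosen after their values were seen. Lists with at least 5 measured members were tested with limma's camera, a two-sided competitive test with a preset correlation between genes of 0.01, and adjusted over the 25 lists. List members without a probe set of their own are not analysed here.

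The fit was tested on simulated data for this comparison, over 18132 genes with 50 genes changed at each size. It recovered 60% of genes changed by 0.3 on the log2 scale, 82% at 0.5, 98% at 1 and 100% at -1, and 9 of 179 calls were false (5.03%). A list shifted by 0.2 was called, and 0 other lists were. Each gene's noise was drawn separately, so this cannot show how often camera falsely calls lists of correlated genes. Far fewer genes were changed in the simulation than passed in the data, so recovery in the data can differ.

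The alternatives were filters on dim genes (mean log2 value of at least 5, or at least the median over genes), quantile normalisation again, median centring, cyclic loess, a variance trend with robust estimation, array weights, the mean of all probe sets or the most variable probe set per gene, the replicate number as a block, and leaving out each array in turn. For lists, camera with an estimated correlation and the rotation test fry were also run. The RNA quality values from the control probe sets were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 arrays against 3. The number of arrays limits the precision of all values.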

Results

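Gene expression was measured in BCPAP, a cell line derived from a human papillary thyroid carcinoma, after lentiviral delivery of a short hairpin RNA. The hairpin was directed against CSF2, the gene of the cytokine GM-CSF (shCSF2), or was a non-targeting control (shCtrl). Each group held 3 arrays, described in the labels as biological replicates, and each array reported 49395 probe sets. Array medians lay between 5.77 and 5.79 on the log2 scale. Values correlated across probe sets with r = 0.998 within groups and r = 0.994 between groups, where probe sets are not independent replicates. No 2 arrays held identical values. The number of arrays limits the precision of every value. The level of CSF2 itself was not analysed here, because none of the probe sets was paired with that gene in the annotation used, so the labels were not checked against the targeted transcript.

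The comparison of shCSF2 with shCtrl asked which transcripts differ in these cells when CSF2 is targeted. The gene with the largest rise was POLE2, a subunit of DNA polymerase epsilon, which was 4.02-fold higher in shCSF2 cells (log2 fold change 2.01 ± 0.06, SE, n = 3 arrays per group). The gene with the largest fall was ACTC1, cardiac alpha actin, which was 3.63-fold lower (log2 fold change -1.86 ± 0.04). By the camera test with a preset correlation, 9 of 25 fixed gene lists were called higher and 4 lower. The 6 of these with the lowest p were the ATF4 stress response, oxidant defence, inflammatory signalling and MAPK output, which were higher, and mitosis and the extracellular matrix, which were lower. None of the 13 calls held with an estimated correlation, where the lowest was adjusted p = 0.0690. This loss does not by itself show correlated members. For antigen presentation, MAPK output and p53 targets the estimated correlation was below the preset 0.01. Most changes were small, with a median absolute log2 fold change of 0.27 among the genes that passed the test.

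Of 18132 genes tested with limma, 5930 (32.7%) passed an adjusted p of 0.05, of which 3037 were higher and 2893 lower in shCSF2 cells. A change of at least 2-fold was reached by 32 of the higher and 25 of the lower genes, and 5499 of the passing genes changed by less than 1.5-fold. In 8459 genes (46.7%) the 3 shCSF2 arrays lay entirely above or below the 3 shCtrl arrays, against 10% by chance. The count of genes lower by 2-fold or more was 16 when all probe sets of a gene were averaged, and the count higher by 2-fold or more was 54 when the most variable probe set was used.

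**Figure D1:**
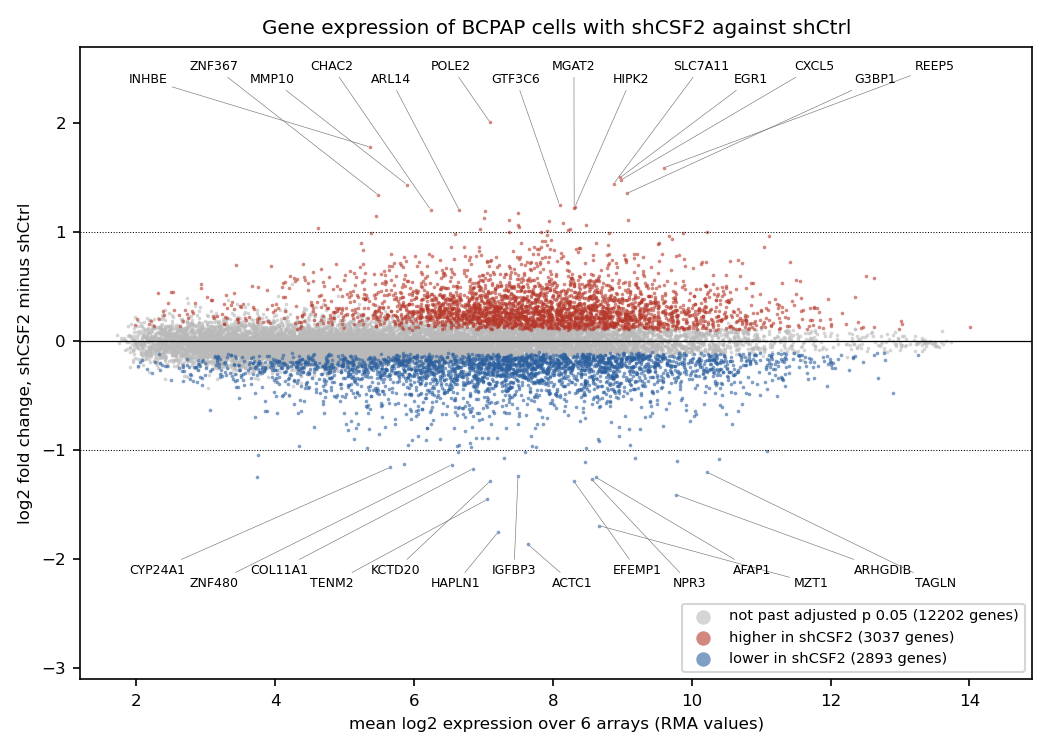
Log2 fold change of shCSF2 over shCtrl (vertical axis) against the mean log2 expression of each gene over 6 arrays (horizontal axis), with 1 point per gene. The 3037 genes higher in shCSF2 are red, the 2893 lower genes blue and all others grey, dotted lines mark 2-fold changes, and the named genes reach from -1.86 (ACTC1) to 2.01 (POLE2).

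Among the 14 named genes with the largest rise, INHBE, an activin-family subunit gene, rose 3.44-fold, from 4.48 ± 0.25 in shCtrl to 6.26 ± 0.12 in shCSF2 cells (mean log2 value ± SD, n = 3). REEP5, which shapes the endoplasmic reticulum, rose 3.01-fold, and EGR1, an immediate-early transcription factor, rose 2.83-fold. CXCL5, a neutrophil-attracting chemokine, was 2.79-fold higher and SLC7A11, the cystine transporter, 2.72-fold higher. MMP10, a matrix metalloproteinase, rose 2.71-fold and G3BP1, a core protein of stress granules, 2.56-fold. The remaining higher genes were ZNF367 (2.53-fold), GTF3C6 (2.38-fold), the kinase HIPK2 (2.35-fold), the N-glycan-processing enzyme MGAT2 (2.34-fold), CHAC2, which degrades glutathione (2.31-fold), and the small GTPase ARL14 (2.30-fold). POLE2, INHBE, MMP10, GTF3C6, CHAC2 and ARL14 were each measured by 1 probe set, and 1 of the 3 probe sets of ZNF367 and 6 of the 9 of HIPK2 passed. With all probe sets of a gene averaged, the log2 fold change was 0.48 for ZNF367 and 0.66 for HIPK2.

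Among the 14 named genes with the largest fall, HAPLN1, which links hyaluronan to proteoglycans, fell 3.37-fold, from 8.09 ± 0.05 to 6.34 ± 0.20 (mean log2 value ± SD, n = 3). MZT1, a component of the gamma-tubulin ring complex, fell 3.23-fold, and the cell-surface teneurin TENM2 fell 2.73-fold. The matrix genes EFEMP1 (2.43-fold) and COL11A1 (2.25-fold) were lower, as were the actin-binding genes AFAP1 (2.38-fold) and TAGLN (2.30-fold). IGFBP3, which binds insulin-like growth factors, fell 2.35-fold, NPR3, a natriuretic peptide receptor, 2.41-fold, and CYP24A1, which inactivates vitamin D, 2.23-fold. KCTD20 fell 2.43-fold. ZNF480 fell 2.19-fold by the probe set used, but 2 of its 4 probe sets passed in each direction, so its direction is uncertain. For ACTC1, 1 of 2 probe sets passed. With all probe sets averaged, ACTC1 was 1.91-fold and ZNF480 1.28-fold lower. The limma adjusted p of the 28 named genes ranged from 8.43e-06 to 0.000186. Of the 22 named genes with more than 1 probe set, 17 had every probe set past the threshold in 1 direction.

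**Figure D2:**
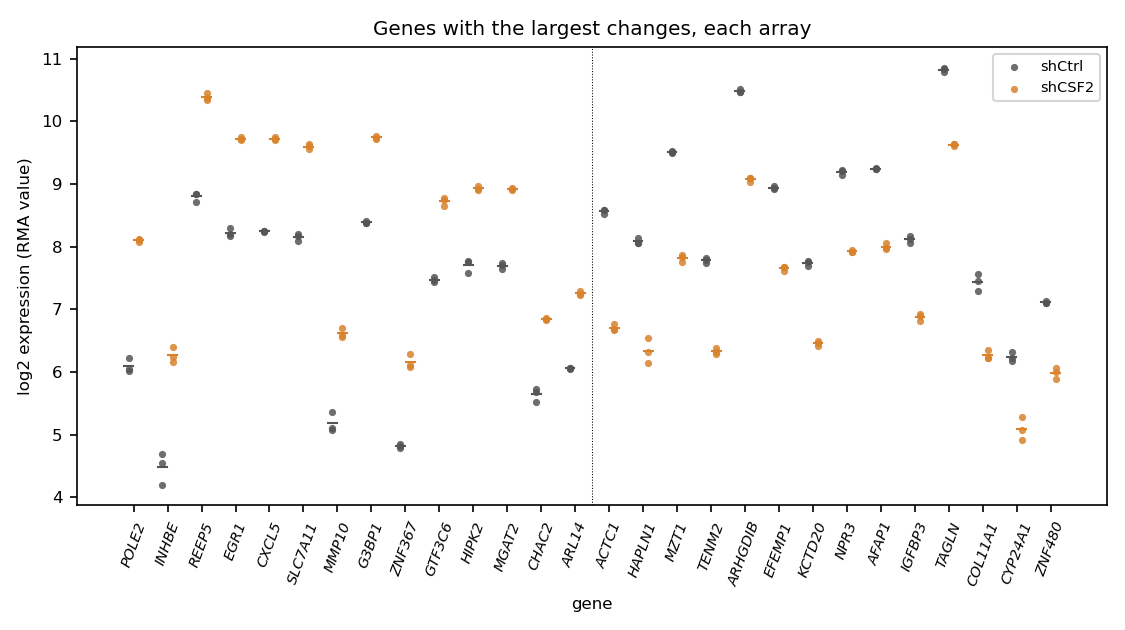
Log2 expression (vertical axis) of the 28 named genes (horizontal axis), with 1 point per array (n = 3 per group) and a bar at each group mean, shCtrl in grey and shCSF2 in orange. The 14 genes left of the dotted line are higher and the 14 right of it lower in shCSF2 cells, and the rule for naming them admitted only genes whose groups did not overlap.

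Genes induced by the transcription factor ATF4 in the integrated stress response formed the most shifted of the 25 gene lists. Of 28 measured members, 23 rose and 1 fell, with a median log2 fold change of 0.51. The cystine transporter gene SLC7A11 (1.44 ± 0.04, log2 fold change ± SE), the mTOR inhibitor gene DDIT4 (1.12 ± 0.04), the sestrin gene SESN2 (1.10 ± 0.05) and the transcription factor gene ATF3 (1.03 ± 0.03) rose most, ATF3 by 0.64 with all probe sets averaged. The member that fell was MTHFD2 (-0.21), a mitochondrial folate enzyme, named after its value was seen. The counts were the same when adjusted over the list alone. The camera test gave an adjusted p of 9.54e-14 for the list, and adjusted p = 0.0690 with an estimated correlation. Of 19 measured targets of NRF2, the regulator of oxidant defence, 11 rose and 0 fell, also when adjusted over the list alone. SLC7A11, which both lists hold, the glutathione synthesis gene GCLM (1.06 ± 0.03), the haem oxygenase gene HMOX1 (0.86 ± 0.06) and the quinone reductase gene NQO1 (0.67 ± 0.03) led this list. Its camera adjusted p was 2.09e-05, and adjusted p = 0.131 with an estimated correlation.

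The unfolded protein response list of the endoplasmic reticulum moved in both directions. Of 22 members, 4 rose and 6 fell, again also when adjusted over the list alone, and the list did not pass (median -0.05, camera adjusted p = 0.389). The transcription factor gene XBP1 rose (0.46 ± 0.04), whereas the disulfide isomerase genes PDIA4 (-0.41 ± 0.03) and PDIA6 (-0.39 ± 0.04) and the calreticulin gene CALR (-0.31 ± 0.04) fell. Of 16 cytosolic heat shock genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone), with BAG3 (0.35 ± 0.03) and HSPH1 (0.29 ± 0.05) higher and the small heat shock protein gene HSPB1 (-0.28 ± 0.05) lower. The median was 0.10 and the camera adjusted p 0.0273, with adjusted p = 0.264 with an estimated correlation. This call was lost without shCtrl replicate 1, where the median was 0.10 and the adjusted p 0.0508, within a range of 0.00716 to 0.264 over all camera settings tried. It was also lost when genes with a mean log2 value under 5, or below the median expression, were left out.

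Of 35 genes of G2/M and mitosis, 27 fell and 0 rose (28 and 0 adjusted over the list alone), with a median log2 fold change of -0.25. The topoisomerase gene TOP2A (-0.67 ± 0.03), the spindle midzone gene PRC1 (-0.67 ± 0.03), the kinesin gene KIF2C (-0.54 ± 0.04) and the cytokinesis gene ANLN (-0.48 ± 0.06) fell most. The camera adjusted p was 1.63e-11, and adjusted p = 0.0730 with an estimated correlation. Of 34 genes of G1/S and DNA replication, 19 rose and 5 fell (21 and 5 adjusted over the list alone), with a median of 0.19. After POLE2, the cyclin gene CCNE2 (0.69 ± 0.07), the GINS complex gene GINS3 (0.66 ± 0.06) and the sliding clamp gene PCNA (0.49 ± 0.04) rose most. For PCNA 1 of 2 probe sets passed, and its value was 0.29 with both averaged, while CCNE2 was 1.05 by its most variable probe set. The 5 that fell, named after their values were seen, were the helicase subunit gene MCM6, the thymidine kinase gene TK1, GINS1, the ribonucleotide reductase gene RRM2 and the cyclin gene CCNE1. The camera adjusted p of this list was 0.000309, and adjusted p = 0.179 with an estimated correlation.

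Of 24 measured p53 targets, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.13. TIGAR, a regulator of glycolysis (0.44 ± 0.06), the sestrin gene SESN1 (0.43 ± 0.10) and the growth arrest gene GADD45A (0.40 ± 0.03) were among those that rose, and CCNG1 (-0.24), a cyclin gene chosen after its value was seen, fell. The camera adjusted p was 0.000725, and adjusted p = 0.0690 with an estimated correlation. By its most variable probe set SESN1 had a log2 fold change of 0.79. The cell cycle inhibitor gene CDKN1A, chosen after its value was seen, did not pass (-0.01 ± 0.03). Among 26 apoptosis regulators, 8 rose and 6 fell, with the same counts adjusted over the list alone, and the list did not pass (median 0.01, camera adjusted p = 0.402). The gene of the death ligand TRAIL, TNFSF10, fell (-0.87 ± 0.10), while the gene of its receptor, TNFRSF10A (0.44 ± 0.04), the pro-apoptotic gene PMAIP1 (0.37 ± 0.04) and the anti-apoptotic gene MCL1 (0.34 ± 0.03, or 0.88 by its most variable probe set) rose.

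Of 29 measured NF-kB targets and inflammatory cytokines, 16 rose and 3 fell (17 and 3 adjusted over the list alone), with a median log2 fold change of 0.17. The chemokine genes CXCL5 (1.48 ± 0.03), CXCL3 (1.03 ± 0.04) and CXCL2 (0.78 ± 0.04) and the transcription factor gene IRF1 (0.84 ± 0.05, or 0.55 with all probe sets averaged) rose most. PTGS2, which makes prostaglandins, and the chemokine genes CXCL6 and CCL20 fell, and are named after their values were seen. By camera the adjusted p was 1.04e-06, and adjusted p = 0.0690 with an estimated correlation. Of 24 genes that report MAPK pathway output, 17 rose and 3 fell (17 and 4 adjusted over the list alone), with a median of 0.26. EGR1 (2.83-fold), the growth regulator gene MYC (0.73 ± 0.03) and the cytokine gene LIF (0.67 ± 0.05) rose, and the receptor gene EPHA4, the MAPK feedback inhibitor gene SPRY1 and the chromatin protein gene HMGA2, chosen after their values were seen, fell. LIF belongs to both lists. In the MAPK list PHLDA1 (0.61 ± 0.03) also rose by the probe set used, but 1 of its 4 probe sets passed in the other direction. Its value was 0.21 with all probe sets averaged. For the MAPK list the camera adjusted p was 8.41e-06, and adjusted p = 0.0690 with an estimated correlation.

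Of 32 interferon-stimulated genes, 14 rose and 4 fell, also when adjusted over the list alone. IFIT2 (0.86 ± 0.05), MX1 (0.53 ± 0.04) and XAF1 (0.49 ± 0.05), antiviral or pro-apoptotic effectors, rose, and the virus-tethering gene BST2 (-0.55 ± 0.05) fell. The median was 0.06 and the camera adjusted p 0.0149, with adjusted p = 0.355 with an estimated correlation, and the call was lost when genes with a mean log2 value under 5, or below the median expression, were left out. Of 19 antigen presentation genes, 12 fell and 2 rose, also when adjusted over the list alone. HLA-F (-0.62 ± 0.08), HLA-B (-0.57 ± 0.04), HLA-DMA (-0.48 ± 0.07) and HLA-C (-0.46 ± 0.03) fell most, although the values of the related class I genes are uncertain because their transcripts can bind each other's probes. With all probe sets averaged, HLA-F was -0.28 and HLA-B -0.38. HLA-DMA was dim in both groups, with a mean log2 value of 4.41 in shCSF2 and 4.88 in shCtrl cells. The 2 higher genes, chosen after their values were seen, were the peptide transporter gene TAP2 and the immunoproteasome gene PSMB10. The median was -0.20 and the camera adjusted p 0.000447, with adjusted p = 0.0690 with an estimated correlation.

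The list of the GM-CSF receptor and JAK-STAT5 signalling, the pathway downstream of the targeted cytokine, did not pass (median -0.07, camera adjusted p = 0.0852). Of its 20 members, 6 fell and 1 rose, also when adjusted over the list alone. The list passed when the genes below the median expression were left out, with a median of -0.26 and an adjusted p of 0.0264, within a range of 0.0264 to 0.211 over all camera settings. That setting dropped the dim members, among them the receptor genes CSF2RA and CSF2RB. CSF2RA (0.01 ± 0.20, mean log2 value 4.14 in shCSF2 cells) and CSF2RB (-0.11 ± 0.10, 5.23) did not pass. Nor did CISH, SOCS1, SOCS2 and SOCS3. These genes were chosen after their values were seen. The helix-loop-helix gene ID1 fell (-0.34 ± 0.04). The signal transducer gene STAT5B (-0.37 ± 0.06) and the adaptor gene GAB2 (-0.36 ± 0.04) also fell by the probe set used, but no longer passed when all probe sets were averaged (-0.07 and -0.11). PIM2 (-0.29 ± 0.08), another of the 6, lost its call in 4 of the 6 fits that left out 1 array. The kinase gene PIM1 (-0.24 ± 0.04) and the signal transducer gene STAT3 (-0.28 ± 0.04), also of the 6, are named after their values were seen. Their values under other settings are not given here. The member that rose was the survival gene BCL2L1 (0.22), chosen after its value was seen.

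Of 33 genes of the mesenchymal state and the extracellular matrix, 19 fell and 3 rose (21 and 4 adjusted over the list alone), with a median log2 fold change of -0.24. The actin-binding gene TAGLN (-1.20 ± 0.04) and the collagen genes COL5A2 (-1.08 ± 0.03), COL4A1 (-1.01 ± 0.03) and COL1A1 (-0.93 ± 0.05) fell most, COL1A1 by 1 of its 5 probe sets. With all probe sets averaged, COL5A2 was -0.69 and COL1A1 -0.25. The N-cadherin gene CDH2, the collagen crosslinking gene LOXL2 and the gelatinase gene MMP9 rose, and are named after their values were seen. By camera the adjusted p was 7.48e-06, and adjusted p = 0.0690 with an estimated correlation. Epithelial markers did not pass as a list (median -0.01, camera adjusted p = 0.566), with 3 of 27 higher and 5 lower, also when adjusted over the list alone. The transcription factor gene ELF3 (-0.59 ± 0.08, or -0.38 with all probe sets averaged) and the plakoglobin gene JUP (-0.48 ± 0.04) fell, and the laminin gene LAMB3 (0.50 ± 0.04) rose. YAP-TAZ targets did not pass either (median -0.04, camera adjusted p = 0.566), with 7 of 23 higher and 8 lower, also when adjusted over the list alone. The matricellular genes CCN1 (-0.41 ± 0.05) and CCN2 (-0.41 ± 0.05) fell, and FJX1 (0.52 ± 0.05) rose.

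Thyroid differentiation genes did not pass as a list (median -0.04, camera adjusted p = 0.378), with 1 of 19 higher and 3 lower, also when adjusted over the list alone. The thyroid transcription factor gene NKX2-1 fell (-0.42 ± 0.04), as did the monocarboxylate transporter gene SLC5A8 (-0.37 ± 0.06), which was near the low end of the arrays' range in both groups (3.24 ± 0.12 in shCSF2 and 3.61 ± 0.04 in shCtrl cells, mean log2 value ± SD, n = 3). The change of SLC5A8 was -0.21 with all probe sets averaged. The counts depend on single arrays, since the higher gene, the hormone receptor gene THRB (0.14 ± 0.04), and IYD (-0.17 ± 0.04), 1 of the 3 lower, lost their calls in 5 and 4 of the 6 fits that left out 1 array.

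Of 29 hypoxia and glycolysis genes, 14 rose and 5 fell (15 and 5 adjusted over the list alone), with a median of 0.10. The mitophagy receptor gene BNIP3L (0.74 ± 0.04), the pyruvate dehydrogenase kinase gene PDK1 (0.51 ± 0.03) and NDRG1 (0.49 ± 0.03) rose most, BNIP3L by 0.40 with all probe sets averaged. The 5 that fell, named after their values were seen, were the peptide hormone gene ADM, the enolase gene ENO2, ANKRD37, the collagen hydroxylase gene P4HA2 and the aldolase gene ALDOA. The camera adjusted p was 0.00317, and adjusted p = 0.131 with an estimated correlation, and the call was lost when genes below the median expression were left out. Of 28 genes of oxidative phosphorylation, 14 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.12. The complex I genes NDUFA1 (-0.36 ± 0.03) and NDUFA2 (-0.34 ± 0.04) and the cytochrome oxidase gene COX7B (-0.33 ± 0.04) fell, while the complex I gene NDUFV2 (0.36 ± 0.03) and the ATP synthase gene ATP5F1A (0.20), the latter chosen after its value was seen, rose. The camera adjusted p was 0.00431, and adjusted p = 0.411 with an estimated correlation.

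Cholesterol biosynthesis did not pass (median -0.05, camera adjusted p = 0.546), with 2 of 18 genes higher and 4 lower, also when adjusted over the list alone. The reductase gene DHCR7 fell (-0.52 ± 0.04) and the epoxidase gene SQLE rose (0.32 ± 0.06, or 0.52 by its most variable probe set). Autophagy and lysosome genes did not pass (camera adjusted p = 0.829), with 6 of 28 higher and 9 lower (9 and 10 adjusted over the list alone). Here the median (0.01) and the mean (-0.02) differed in sign, and the test leaned lower. The proton pump gene ATP6V1H (0.91 ± 0.07) rose, and the autophagosome gene WIPI1 (-0.51 ± 0.03) and the cathepsin gene CTSB (-0.41 ± 0.03) fell. Angiogenic factors and receptors did not pass (median 0.01, camera adjusted p = 0.281), with 5 of 22 higher and 4 lower, also when adjusted over the list alone. The co-receptor gene NRP1 (0.85 ± 0.05, or 0.45 with all probe sets averaged) and the ligand genes ANGPTL4 (0.53 ± 0.05) and PGF (0.51 ± 0.05) rose, and FGF1 (-0.66 ± 0.04) fell.

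Markers of other cell types did not pass as lists. Of 20 myeloid markers, 1 fell and 0 rose (camera adjusted p = 0.281), the one being LAPTM5 (-0.18 ± 0.04). Of 16 lymphocyte markers, 0 passed (camera adjusted p = 0.309), with the largest differences in CD2 (-0.24 ± 0.08) and GZMB (-0.23 ± 0.08). CD2 passed only without shCtrl replicate 3 among the fits that left out 1 array (-0.31), and was -0.07 with all probe sets averaged. GZMB was -0.14 without shCSF2 replicate 3. Of 19 fibroblast and endothelial markers, 4 fell and 1 rose (3 and 1 adjusted over the list alone), and the list did not pass (median -0.13, camera adjusted p = 0.0852). THY1, a fibroblast surface gene that other cells also express, fell (-0.61 ± 0.04), and S100A4 (0.28 ± 0.03) rose. TEK (-0.25 ± 0.08), 1 of the 4 that fell here and of the 4 in the angiogenic list, lost its call in 5 of the 6 fits that left out 1 array.

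Of the 25 lists, camera called 9 higher and 4 lower with a preset correlation between genes of 0.01, and 0 with an estimated correlation, where 9 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list moves without comparing it with other genes, called 11 lists higher and 14 lower. It thus called every list, and does not tell the lists apart. As a sign of RNA quality, the log2 value of the 3' probe set of GAPDH minus that of its 5' probe set was -0.01 ± 0.01 in shCSF2 and -0.03 ± 0.01 in shCtrl cells (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible). The same difference for ACTB was 0.61 ± 0.05 and 0.59 ± 0.05 (exact two-sided permutation p = 0.6).

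**Figure D3:**
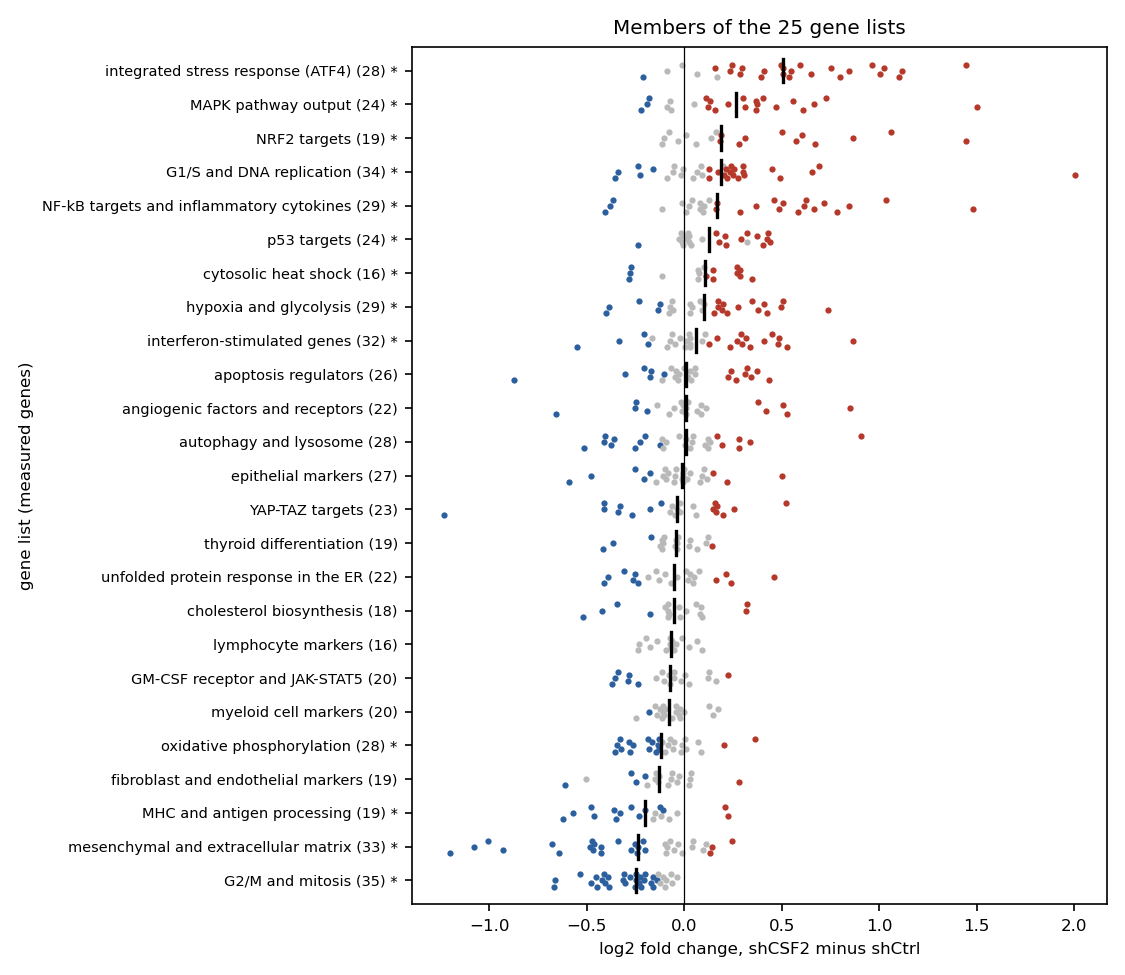
Log2 fold change of shCSF2 over shCtrl (horizontal axis) for each measured member of the 25 gene lists (vertical axis, number measured in brackets), red for members that rose, blue for those that fell and grey for those not passing. Black bars are list medians, from -0.25 for G2/M and mitosis to 0.51 for the integrated stress response, and asterisks mark the 13 lists called by camera with the preset correlation.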

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

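The tests of explanations and of other splits given here were chosen after the results were seen.

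Probe sets without a single gene in the annotation took no part in the gene comparison, yet some changed between the groups. Of 2473 probe sets not listed in the annotation, 628 passed in the limma fit over all probe sets, and 6 were higher in shCSF2 cells by at least 2-fold. The highest of these had a log2 fold change of 1.36 ± 0.08 (SE, n = 3 arrays per group). Of 1832 probe sets paired with several genes, 455 passed, with 1 higher and 6 lower by at least 2-fold. What these probe sets measure was not examined.

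With 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. The other splits each mix both groups on both sides, so a difference between the groups adds to their spread and lowers their gene counts. They can also carry part of that difference into the list calls. Their counts therefore do not show what arrays without a difference would give. In limma, 1 split, the real one, gave as many genes, with 5930 passing against 0 at most in the others, where up to 497 genes had an unadjusted p under 0.05, against 7694 in the real split. For genes changed by 2-fold or more the real split again was the 1 with as many, at 57 against 0. For lists called by camera with the preset correlation, the real split was the 1 with as many, at 13 against 9, and the others gave 2 or more each.

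In the G1/S list 19 of 34 genes rose and 5 fell, and in the G2/M list 27 of 35 fell. Both list calls were lost with an estimated correlation (adjusted p = 0.179 and adjusted p = 0.0730). The difference between the list medians was 0.44, outside the 0.171 that bounded 99% of 10000 pairs of random lists of matched mean expression (permutation p = 1e-04, the smallest they can give), which argues against a trend with signal intensity. A smaller share of cycling cells as the only change would lower both lists. The 95% bootstrap interval of the G1/S median over members, taken as independent, ran instead from 0.0666 to 0.237. That of G2/M ran from -0.314 to -0.171. These intervals restate the pattern that prompted the question. They leave open a smaller share of cycling cells next to a separate rise of G1/S genes, of which 5 fell. Cell density at harvest, the spread of cells over the cycle and an effect of the hairpin on other transcripts stay open, since none was tested.

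In the ATF4 list 23 of 28 genes rose, and its call was lost with an estimated correlation (adjusted p = 0.0690). The 3' minus 5' values of GAPDH and ACTB differed between groups by at most 0.0242, so these transcripts show no large difference in RNA integrity. They cannot show the integrity of other transcripts, or how far the ATF4 list would move with it. A response to endoplasmic reticulum stress as a whole would raise its own list, whose median had a 95% bootstrap interval of -0.184 to 0.0392, below that of the ATF4 list, 0.291 to 0.697. Part of that response stays open, because XBP1 and 3 other members rose. Whether the pattern follows from CSF2, from another target of the hairpin or from culture conditions was not tested.

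Single genes changed by more than 2-fold against a background of small changes. In 20 of the 22 named genes with several probe sets (90.9%), at least 2 passed in the same direction. A faulty probe set is thus an unlikely cause of the direction for most of these. The size is not covered, since 1 probe set passed by the naming rule and another could pass at any size. With all probe sets averaged, 36 of the 57 genes changed by 2-fold or more stayed so. Over all settings, each gene's own value closest to no change was 0.66 for HIPK2, 0.88 for MGAT2, -0.84 for AFAP1 and -0.97 for KCTD20. It was -0.35 for ZNF480, 0.48 for ZNF367 and -0.94 for ACTC1. A faulty probe set stays open for the 6 genes with 1 probe set, for ACTC1 and ZNF367, and for ZNF480. ZNF480 is among the 20 but has 2 probe sets passing each way, and probe sets can share target sequence. A regional copy-number difference as a common cause would move neighbours too, but the 4 flanking measured genes had a median log2 fold change in the gene's direction of 0.0351 over the 28 genes (upper quartile 0.174). The signal level of the flanking genes is not given here, and dim ones could hardly show such a move, which limits this comparison. A copy-number difference stays open for single genes whose flanking median was higher, such as HAPLN1 (0.31), POLE2 (0.29), its neighbour MGAT2 (0.23) and CYP24A1 (0.22). The same holds for ZNF480 (0.40 in the lower direction), but only if that gene fell, which is uncertain. Silencing of other transcripts by the hairpin stays open for genes that fell, since the hairpin sequence was not used here.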

How the results depend on the processing

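The counts of genes past the threshold stayed within 1.5 times of the reported ones under every alternative run. Leaving out each array in turn gave 2552 to 2738 higher and 2267 to 2529 lower genes, 32 to 35 and 23 to 27 of them by 2-fold or more, and 8 to 9 lists higher and 4 lower. The mean of probe sets gave 16 genes lower by 2-fold or more, for which the cause was not tested. The probe set of largest variance, which favours probe sets that differ between the groups, gave 54 higher by 2-fold or more. Camera with an estimated correlation called 0 lists higher and 0 lower. A higher correlation is not the whole cause, since estimates were under the preset 0.01 for antigen presentation (0.00466), MAPK output (0.00863) and p53 targets (-0.0121). The camera p before adjustment still rose, from 0.000143 to 0.0166 for antigen presentation and from 0.000261 to 0.0155 for p53 targets. Loss of these calls thus does not show that their members are correlated. Fry, which does not compare a list with other genes, called 11 lists higher and 14 lower, and so every list. Rescaling moved the median of all genes by less than 0.1.

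The replicate number was not taken as a pairing, because no label says that it marks a shared batch. Same-numbered replicates deviated together with correlations of 0.03, 0.05 and 0.03 across probe sets. The replicate block gave 2798 higher and 2671 lower genes, 32 and 25 by 2-fold or more, and 9 and 4 lists. Under it IYD and TEK no longer passed and GZMB did.

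For the named genes, 1797 values kept direction and side of the threshold, 29 lost and 3 gained a call, and 3 reversed. TEK was 0.0065 with the mean of probe sets and 0.24 with the probe set of largest variance, and PDPN was 0.041 with the mean of probe sets. The cause was not tested. PIM2, IYD, THRB and TEK lost their calls in 4, 4, 5 and 5 of the 6 fits without 1 array, with log2 fold changes of -0.37 to -0.23, -0.20 to -0.15, 0.12 to 0.17 and -0.34 to -0.20. STAT5B, GAB2, TP53INP1, IYD and THRB lost theirs with the mean of probe sets. For lists, 415 values kept their call, 19 lost and 13 gained one, and the thyroid list reversed to a median of 0.064 among genes with a mean log2 value of at least 5, where fewer genes were tested. Medians that were just above 0 in the main fit also crossed it in some setting. The lowest were -0.019 for apoptosis regulators, -0.0033 for angiogenic factors and receptors and -0.060 for autophagy and lysosome. CSF2 gave no value under any setting. Values near the low end of the arrays' range are compressed, which limits what dim genes can show.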

Other observations

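These gene families were chosen after the values were seen, partly because of genes named in the report, so counts and values are given, and the enrichment tests run on these families are left out because they would reuse those genes. Of 43 collagen genes, 18 fell and 0 rose (median log2 fold change -0.13), and 11 of the 43 also stand in the fixed lists. Outside those lists, COL8A1 (-0.68 ± 0.04, SE, n = 3 arrays per group) and COL12A1 (-0.59 ± 0.05) fell. Of 29 genes of actins, myosin light chains and their kinase, tropomyosins, calponins and transgelins, which include ACTC1 and TAGLN, 15 fell and 0 rose (median -0.18). MYL9, a regulatory myosin light chain of smooth muscle and non-muscle cells, fell 2.15-fold (-1.10 ± 0.04), and the calponin gene CNN3 fell (-0.39 ± 0.03).

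Of 19 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 13 rose and 2 fell (median 0.18), and 4 of them also stand in the ATF4 list. GARS1 (0.59 ± 0.04) and CARS1 (0.50 ± 0.04) were among those that rose, while QARS1 and HARS1 fell. Of 73 mitochondrial ribosomal protein genes, 24 rose and 10 fell (median 0.07). Of 44 proteasome genes, 16 rose, led by PSMD5 (0.40 ± 0.06), and 4 fell (median 0.05). Of 73 cytosolic ribosomal protein genes, 2 rose and 4 fell (median -0.02), and their median was 0.0023 after cyclic loess. The medians of the other families kept their sign under quantile normalisation, median centring and cyclic loess.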
